A study of Mus musculus with 7 samples.

How the data were processed

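RNA of whole mouse embryos on embryonic day 9 was hybridised to Affymetrix Murine Genome 430A arrays, which carry many 25-base probes per gene and are read as brightness. Per the labels, the embryos were dissected from yolk sac and amnion, genotyped from yolk sac DNA, and pooled as 2 littermates of one genotype per array. Of the 7 arrays 2 were wild type, 3 heterozygous and 2 knockout for Adnp, and groups and replicate numbers were taken from the sample titles. The pools came from separate embryos, and how litters were divided among them is not given in the sources used here.

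The deposited values are probe set intensities on a linear scale, summarised by the authors with MAS5, per the submitters' processing notes, which combines each probe set's perfect-match and mismatch probes into 1 signal per array. The software version, scaling target and detection calls are not given in the sources used here. The values themselves show scaling per array: the mean after leaving out 2% of probe sets at each end was 150.0 to 150.1 on every array. Such scaling makes changes relative to the whole array, so a general change in RNA per embryo would not be seen. MAS5 signals are noisy for dim probe sets, which is why a filter on brightness was used.

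The value table holds 22690 probe sets, 64 of them array controls. Of the other 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were not listed there, and only those with 1 symbol named genes (12393 symbols). An update through the Entrez identifiers of a gene table for GRCm38.p6 changed 0 symbols, and 29 probe sets had an identifier outside that table. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the gene table served only for names and for which genes are neighbours. Signals were taken as log2(signal + 3.8), 3.8 being the 10th percentile of all values, so log2 changes of dim genes are understated. A gene was represented by its brightest probe set over all arrays, and genes whose mean log2 signal lay under the 40th percentile of probe sets (38.1 as signal plus pseudocount) were left out, which left 8019 genes. Among genes with over 1 probe set past the filter and any past the threshold, 115 in all, 15 had probe sets that went in opposite directions.

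Differences between genotypes were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), in 1 fit over all 7 arrays with genotype as the only term, which left 4 residual degrees of freedom beside 6.19 prior ones. P-values are two-sided and Benjamini-Hochberg adjusted over the 8019 genes in each comparison, with a threshold of 0.05. Every adjusted p of a gene in the text is limma's from this fit, and every one of a list is camera's, unless another test is named. The comparisons were knockout with wild type, heterozygous with wild type and knockout with heterozygous, and the genes past the threshold in both knockout comparisons were counted. Arrays are given as signal means ± SD.

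For gene lists, limma's camera with a preset correlation of 0.01 compared each list's changes with those of all other genes, with Benjamini-Hochberg adjustment over the 18 lists of at least 5 measured genes. camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. The 22 lists hold 498 genes, of which 444 had a probe set with 1 symbol and 318 were measured. They cover visceral endoderm, plasma proteins of yolk sac endoderm and liver, metallothioneins and cathepsins, trophoblast, decidua, primitive erythroid cells, endothelium, macrophages, neural progenitors and brain patterning, neurogenesis, heart, somites and paraxial mesoderm, neural crest and pharyngeal arches, Hox genes, pluripotency and primitive streak, p53 targets, hypoxia and glycolysis, cell cycle, cholesterol, imprinted genes, ADNP partners and chromatin regulators, and sex-linked genes. They came from textbook knowledge. The visceral endoderm list and the list of metallothioneins and cathepsins follow gene families that the study itself named on these arrays.

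Named genes were taken by rule. Against wild type these were the 12 largest rises and 12 largest falls among genes past the threshold in which every knockout array lay beyond every wild-type array, and up to 4 members with the largest change from each list that passed or had a member past the threshold. In the other comparisons they were the 5 largest in each direction, or the 5 of smallest p where fewer passed. Hes6, which completes a count of 4 genes, and Rnf17 were named after their values were seen. So were Ctsz, Ctsa, Snai1, Sulf2, Dido1 and Sdc4, called genes near Adnp. Rnf17 and these genes near Adnp are not among the 50 named genes that were followed with each array left out. The test, the lists, the rule and the alternatives (pseudocount, filter, scaling, trend, arrays in the fit, array weights, replicate block, choice of probe set, thresholds and leaving out each array) were set before the data were examined. Fits with a visceral endoderm score or a Y-linked score as a covariate, each the mean log2 signal of those genes per array, were added after seeing the data.

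The fit was tested on simulated data with the real means of the 8019 genes and spreads drawn from limma's estimated prior, with 200 genes changed. For knockout with wild type it recovered 10% of genes changed 1.5-fold, 62% of those changed 2-fold, 94% at 4-fold and 100% at 8-fold, with 6 unchanged genes called. For knockout with heterozygous it recovered 28%, 74%, 98% and 100%, with 4 unchanged genes called, and for heterozygous with wild type 16%, 72%, 100% and 100%, with 8. Shared wild-type arrays were allowed for by 100 simulations of unchanged groups. With groups of 2 and 3 arrays, no count over other splits of the samples and no test for single outlying arrays was made. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.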

Results

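Gene expression was measured in whole mouse embryos on embryonic day 9 that carried 0, 1 or 2 intact copies of Adnp, the gene of a homeodomain and zinc-finger protein that is needed for development past mid-gestation. Wild-type embryos were measured on 2 arrays, heterozygous embryos on 3 and knockout embryos on 2, and RNA pooled from 2 littermates of one genotype went on each array, so that 14 embryos gave 7 arrays. The replicate is the pool, and all values are MAS5 signals on a linear scale. Median signals were 55.5 to 57.4 on the 7 arrays, and the arrays correlated with Pearson's r from 0.947 to 0.974 across genes, which are not independent replicates. The small number of arrays limits the precision of every value below. The study's question was which genes lie downstream of ADNP. Log2 differences are on the log2(signal + pseudocount) scale, and every adjusted p of a gene is limma's.

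The targeted gene could not be checked on these arrays. The only probe set annotated to Adnp is also annotated to its neighbour Dpm1, so its signal is not a measure of either gene alone. It read 1781 ± 140.5 in the knockout (SD, n = 2), 961.4 ± 90.8 in wild type (n = 2) and 1099 ± 106 in heterozygotes (n = 3). The knockout was above wild type by 0.89 on the log2 scale (SE 0.12, limma, adjusted p = 0.00511) and above the heterozygotes by 0.70 (adjusted p = 0.00716). Without knockout replicate 1 the first difference was 0.81 with an adjusted p of 0.0606, and it lost its call with the visceral endoderm score (adjusted p = 0.12) or the Y-linked score (adjusted p = 0.50) as a covariate. A probe set for Dpm1 alone was above wild type by 0.44 (SE 0.17, limma, adjusted p = 0.183) and did not pass. Above the heterozygotes it was by 0.48 (adjusted p = 0.0907), which did not pass either. No loss of Adnp RNA in the knockout can be read from the shared probe set. The genotypes therefore rest on the labels, which come from typing of yolk sac DNA.

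Knockout embryos differed from wild type in 266 of 8019 genes. The largest rises included genes of the visceral endoderm, the absorptive and secretory layer around the early embryo, and a smaller number of genes of the heart, somites and nervous system fell. Apoa1, an apolipoprotein of high-density lipoprotein, went from 78.5 ± 90.9 to 1551 ± 220 (SD, n = 2 each) and Cubn, the endocytic receptor cubilin, from 44.7 ± 37.9 to 679.2 ± 29.7. Myl2, a myosin light chain of ventricular muscle, fell from 561 ± 40.0 to 89.8 ± 7.92, and Pax1, a transcription factor of the sclerotome, from 64.0 ± 2.62 to 8.90 ± 0.57. Bnip3, a mitochondrial protein induced by low oxygen, rose from 478.6 ± 17.8 to 1599 ± 34.9 and had the smallest adjusted p of all genes (limma, 8.47e-05).

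Of the 266 genes, 157 rose and 109 fell, and 137 changed by at least 2-fold, 95 up and 42 down. An unadjusted p under 0.05 was reached by 1528 genes (19.05%), where 401 would be reached by chance. The count was 57 without wild-type replicate 2, 75 without knockout replicate 1, 36 without knockout replicate 2 and 417 without heterozygous replicate 1, which in this fit only informs the spread. The knockout arrays also stood apart in the mean log2 signal of the visceral endoderm list (8.74 and 8.95, against 5.91 to 7.30 on the other 5 arrays), and wild type stood apart in that of 3 Y-linked genes (3.14 and 3.56, against 5.11 to 6.11). With either score as a covariate, an alternative chosen after seeing the data, 0 genes passed. Neither score overlapped between knockout and wild type, so that fit can hardly tell genotype and score apart. The absence of calls therefore leaves open how far the visceral endoderm score accounts for the changes. The heterozygous pools had Y-linked scores of 5.4, 5.99 and 5.11, above wild type as well, yet 0 genes passed between these genotypes. Their list medians against wild type were -0.13 for visceral endoderm, 0.01 for hypoxia and glycolysis and -0.02 for somites. Between knockout and heterozygous 144 genes still passed with the Y-linked score. These values argue against the sexes of the pools as the source of the changes in these lists. With the visceral endoderm score Myl2 had a change of -2.54 and Bnip3 one of 1.66, which did not pass (adjusted p = 0.0664 each).

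**Figure D1:**
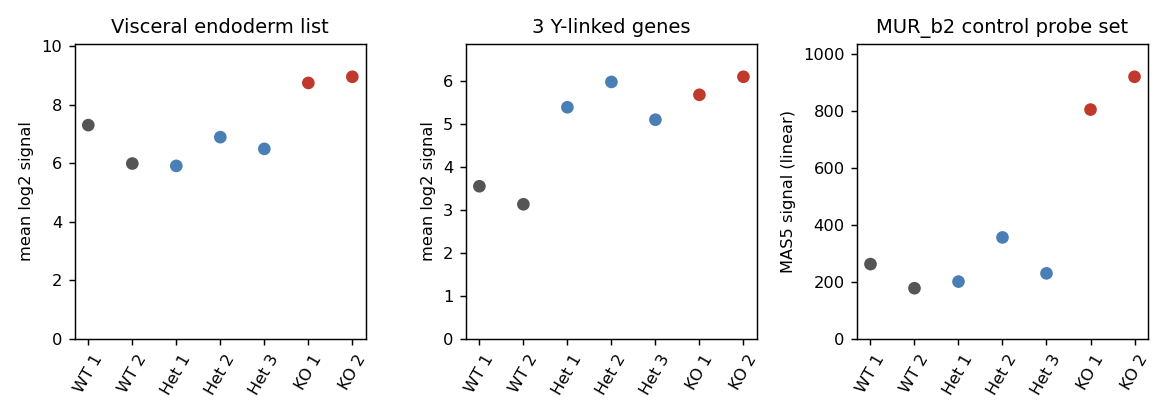
Mean log2 signal of the visceral endoderm list, mean log2 signal of 3 Y-linked genes and MAS5 signal of the array control MUR_b2 (vertical axes) on each of the 7 arrays (horizontal axis; WT, wild type; Het, heterozygous; KO, knockout; points are arrays). Both knockout arrays lie above the other 5 in the first panel and in the MUR_b2 panel, and both wild-type arrays lie below the other 5 in the Y-linked panel.

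Of the 50 genes named here as past the threshold between knockout and wild type, 14 passed whichever array was left out: Rhox5, Tex19.1, Apoe, Ctsh, Ctsc, Tcfl5, Mt1, Mt2, Bnip3, Ddit4, Myl2, Nppa, Pax1 and Col26a1. Calls were lost without knockout replicate 2 for 33 of the 50 genes, without wild-type replicate 2 for 26, without knockout replicate 1 for 25, without wild-type replicate 1 for 6 and without heterozygous replicate 2 or 3 for 2 and 5.

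**Figure D2:**
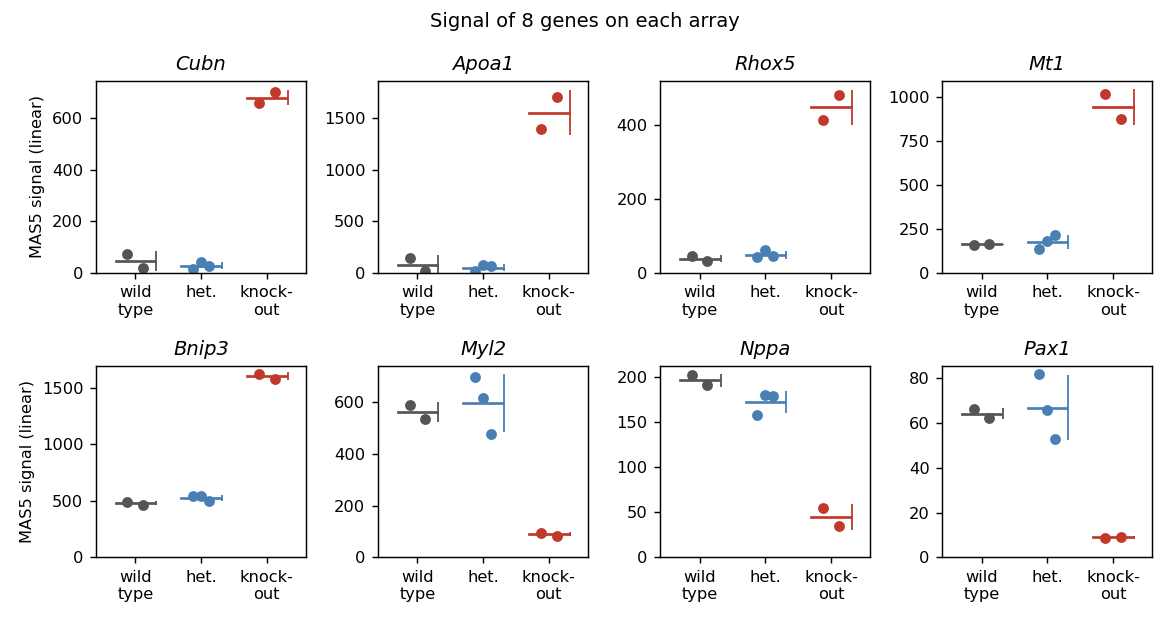
MAS5 signal (linear scale, vertical axis) of 8 genes on each of the 7 arrays, by genotype (horizontal axis; het., heterozygous). Points are arrays, horizontal lines are group means and vertical lines are ± 1 SD (n = 2 wild type, 3 heterozygous, 2 knockout). The knockout arrays lie above all others for Cubn, Apoa1, Rhox5, Mt1 and Bnip3 and below all others for Myl2, Nppa and Pax1.

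The 12 largest rises included lipid carriers and genes weighed further on as germline genes. Among lipid and vitamin carriers, the log2 changes were 4.91 for Apoa1 (SE 0.89, limma, adjusted p = 0.0171), 3.00 for Apoe (SE 0.32, 0.00129), 2.99 for Apob (SE 0.40, 0.00392) and 2.79 for Rbp4, the plasma carrier of retinol (SE 0.65, 0.0462). Cubn rose by 4.08 (SE 0.53, adjusted p = 0.00365), Spink1, a secreted trypsin inhibitor, by 4.45 (SE 0.82, 0.0181) and Ctsh, a lysosomal protease, by 2.71 (SE 0.31, 0.00193). With 1 array left out, the changes ran from 1.64 to 3.95 for Rbp4, 2.82 to 6.08 for Spink1 and 3.40 to 6.43 for Apoa1. Another set was weighed further on as germline genes: Rhox5, an X-linked homeobox gene, rose by 3.45 (SE 0.24, adjusted p = 9.35e-05), Tex19.1 by 3.04 (SE 0.23, 0.000168), Fmr1nb by 2.92 (SE 0.36, 0.00269) and Tcfl5, a testis transcription factor, by 2.67 (SE 0.32, 0.0024). Kdm5d, a Y-linked histone demethylase, stood at 79.1 ± 33.7 against 7.15 ± 4.03 in wild type (log2 2.91, SE 0.41, adjusted p = 0.00559). The labels call the pools mixed in sex, yet the Y-linked signals were near the floor in both wild-type pools. Kdm5d was above wild type in the heterozygotes too, by 2.59 (limma, adjusted p = 0.301, not passed). This difference therefore goes with the sexes of the pooled embryos and is not particular to the knockout. Cubn, Apob, Fmr1nb and Kdm5d lost their calls without knockout replicate 2 (adjusted p 0.0514 to 0.0677), Spink1 and Apoa1 without either knockout array (0.103 to 0.135), Apoa1 also without wild-type replicate 2 (0.103), and Rbp4 without any of these or heterozygous replicate 3 (0.0808 to 0.251).

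The largest falls were those of Rad51c, a gene of homologous recombination (-2.78, SE 0.43, limma, adjusted p = 0.00848), and Trp53rka (-2.72, SE 0.36, 0.00392), and Abhd8 (-1.60, SE 0.31, 0.0215) was among the 12 too. Of muscle and skeletal genes, Myl2 fell by 2.59 on the log2 scale (SE 0.17, limma, adjusted p = 9.35e-05), Nppa, the atrial natriuretic peptide, by 2.08 (SE 0.20, 0.000744), Pax1 by 2.42 (SE 0.27, 0.0018) and Col26a1, a collagen, by 1.93 (SE 0.19, 0.000744). Neuronal genes were Elavl3, an RNA-binding protein of new neurons (-2.60, SE 0.48, adjusted p = 0.0181), Fabp7, the fatty acid-binding protein of radial glia (-2.30, SE 0.32, 0.00555), Sst, somatostatin (-1.76, SE 0.33, 0.0205), Fez1, an axonal transport adaptor (-1.54, SE 0.20, 0.00371) and Nefl, the light neurofilament (-1.48, SE 0.33, 0.0396). The other probe set of Rad51c gave a smaller fall of 1.33, also past the threshold. Knockout signals of Rad51c, Trp53rka, Elavl3 and Pax1 were 8.45 to 10.1, within a few units of the pseudocount of 3.8, so the size of these falls is uncertain. Rad51c lost its call without wild-type replicate 2 (adjusted p = 0.0582), Fabp7 without knockout replicate 1 (0.0547), and Trp53rka and Fez1 without knockout replicate 2 (0.0514 each). Elavl3, Sst, Abhd8 and Nefl lost theirs without wild-type replicate 2 or either knockout array (0.0859 to 0.263), and Nefl also without heterozygous replicate 3 (0.0736).

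The visceral endoderm list rose as a group. Of its 23 measured genes 17 rose, 0 fell and 6 did not pass, or 21 risen when adjusted over the list alone, with a median log2 change of 1.98 (camera, adjusted p = 6.73e-23; adjusted p = 0.108 with an estimated correlation). Apoa1 and Cubn had its largest rises past the threshold. Ttr, the thyroxine carrier (log2 difference 3.45, limma, adjusted p = 0.109), and Apoc2 (3.95, 0.122) did not pass, though Ttr did without wild-type replicate 1 (0.022) and Apoc2 without that array (0.045) or heterozygous replicate 1 (0.0322). Levels also varied within genotypes: Ttr read 665.5 and 60.8 in the wild-type pools, 44.7, 431.3 and 86.3 in the heterozygous pools, and 1937 and 2654 in the knockout. With 1 array left out, the log2 difference ran from 1.76 to 5.14 for Ttr and from 2.18 to 5.71 for Apoc2. The study itself named such genes on these arrays, so the list is not independent evidence of its direction. With the Y-linked score as a covariate the median was -0.067 (camera, adjusted p = 0.996). Of 5 plasma proteins made by yolk sac endoderm and liver, 1 rose, Serpinf2 (0.93, limma, adjusted p = 0.0437), and 4 did not pass, or 4 risen when adjusted over the list alone (median 0.93, camera, adjusted p = 0.00492; adjusted p = 0.11 with an estimated correlation). The median was 0.41 without wild-type replicate 2. This list lost its camera call with the visceral endoderm score (median 0.89, adjusted p = 0.237) or the Y-linked score (0.22, 0.949) as a covariate. Serpinf2 lost its call without any single array other than heterozygous replicate 1 (adjusted p 0.054 to 0.285). The differences of F2, prothrombin (1.10, adjusted p = 0.0542), Tfpi (0.59, 0.122) and Spp2 (1.37, 0.213; 0.0302 without wild-type replicate 1) did not pass.

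Metallothioneins and cathepsins, which bind metal ions and degrade proteins in lysosomes, rose together. Of 10 measured genes 8 rose, 0 fell and 2 did not pass, or 9 risen when adjusted over the list alone (median 1.18, camera, adjusted p = 2.35e-15; adjusted p = 0.019 with an estimated correlation). Mt1 rose by 2.51 (SE 0.19, limma, adjusted p = 0.000168), Mt2 by 2.0 (SE 0.23, 0.00193), Ctsc by 2.03 (SE 0.18, 0.000497) and Ctsh by 2.71. These families too were named by the study on these arrays, which makes the list no independent evidence. Its median was 1.02 with the visceral endoderm score as a covariate (camera, adjusted p = 3.35e-10; adjusted p = 0.106 with an estimated correlation) and 1.00 with the Y-linked score (7.69e-05; 0.27).

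Genes of the response to low oxygen and of glycolysis rose as well. Of 23 measured genes 10 rose, 0 fell and 13 did not pass, or 20 risen when adjusted over the list alone (median 0.66, camera, adjusted p = 9.94e-18; adjusted p = 0.0297 with an estimated correlation). Bnip3 rose by 1.73 (SE 0.10, limma, adjusted p = 8.47e-05), Ndrg1 by 1.26 (SE 0.21, 0.0129) and Pfkp, a phosphofructokinase, by 1.24 (SE 0.17, 0.00555). Aldoc, a glycolytic aldolase, did not pass (1.40, 0.0824; 0.0078 without heterozygous replicate 1). Ndrg1 and Pfkp lost their calls without either knockout array, and Ndrg1 also without wild-type replicate 2 (adjusted p 0.0514 to 0.123). With the visceral endoderm score, which was higher on both knockout arrays, as a covariate, the list's median was 0.26 (camera, adjusted p = 7.37e-05; adjusted p = 0.106 with an estimated correlation), and with the Y-linked score 0.38 (0.00861; 0.52). Genes of cholesterol synthesis and uptake had a median of 0.51, with 2 of 13 risen, 11 not passed and 9 risen when adjusted over the list alone (camera, adjusted p = 5.07e-07; adjusted p = 0.0401 with an estimated correlation). The risen members were Fdps, farnesyl diphosphate synthase (0.73, SE 0.11, limma, adjusted p = 0.00635), and Hmgcs1, HMG-CoA synthase (0.64, SE 0.09, 0.00641). Both lost their calls without wild-type replicate 2 or knockout replicate 2, and Fdps without knockout replicate 1 (0.0502 to 0.091). Msmo1 (0.72, adjusted p = 0.0633) and Mvd (0.72, 0.0826) did not pass with all arrays but did without heterozygous replicate 1 (0.0499 and 0.0309). The cholesterol list's median was 0.28 with the visceral endoderm score as a covariate (camera, adjusted p = 0.000941; adjusted p = 0.19 with an estimated correlation) and 0.53 with the Y-linked score (0.00861; 0.355).

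The somite and paraxial mesoderm list fell. All 11 measured members had negative log2 differences (median -0.62), 2 of them past the threshold and 8 when adjusted over the list alone (camera, adjusted p = 4.01e-07; adjusted p = 0.0297 with an estimated correlation). Pax1 fell by 2.42 and Meox1, a homeobox gene of the somites, by 1.23 (SE 0.18, limma, adjusted p = 0.00622; 0.0677 without knockout replicate 2). Its relative Meox2 (-1.47, 0.0646) and Uncx, a homeobox gene of the posterior sclerotome (-1.0, 0.0707), did not pass, though Meox2 did without knockout replicate 1 (0.0256). The list's median was -0.77 with the visceral endoderm score as a covariate (camera, adjusted p = 3.22e-05; adjusted p = 0.106 with an estimated correlation) and -0.40 with the Y-linked score (0.00747; 0.27).

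Heart genes fell in a small part of their list. Of 27 measured genes 2 fell, Myl2 and Nppa, and 25 did not pass, or 5 fallen and 1 risen when adjusted over the list alone (median -0.19, camera, adjusted p = 0.00632; adjusted p = 0.385 with an estimated correlation). The camera call was lost without wild-type replicate 1 (median -0.044, adjusted p = 0.171) or knockout replicate 2 (-0.071, 0.0613), and the median was -0.33 without knockout replicate 1. Nppb, the B-type natriuretic peptide (-0.70, limma, adjusted p = 0.113), and Smpx, a small muscle protein (-0.94, 0.0597), did not pass. The median was -0.47 when the visceral endoderm score was a covariate (camera, adjusted p = 8.13e-06; adjusted p = 0.22 with an estimated correlation) and -0.61 when it was the Y-linked score (0.00109; 0.52).

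Neural genes fell in part. In the list of neural progenitor and brain patterning genes 7 of 25 fell and 18 did not pass, or 7 fallen and 2 risen when adjusted over the list alone (median -0.095, camera, adjusted p = 0.0305; adjusted p = 0.11 with an estimated correlation). Fallen members included Fabp7 and Lhx2, a forebrain homeobox gene (-1.07, limma, adjusted p = 0.0314). En1, a midbrain and hindbrain homeobox gene (1.12, 0.076), and Olig2 (-1.15, 0.239) did not pass. Of 18 neurogenesis genes 4 fell and 14 did not pass, or 6 fallen when adjusted over the list alone (median -0.38, camera, adjusted p = 0.000373; adjusted p = 0.402 with an estimated correlation). These were Elavl3, Nefl, Elavl4, a relative of Elavl3 (-1.37, adjusted p = 0.0137), and Hes6 (-1.10, 0.0216), while Neurod1 (-1.35, 0.0716) did not pass. With no filter on dim probe sets the progenitor median was 0.016, against camera's direction (adjusted p = 0.0351). The progenitor list lost its call without wild-type replicate 1 (median -0.17, camera, adjusted p = 0.0621) or knockout replicate 2 (-0.16, 0.0613), and its median was -0.22 without knockout replicate 1. The neurogenesis list lost its call without wild-type replicate 2 (median -0.045, 0.11), and its median was -0.84 without wild-type replicate 1. With the visceral endoderm score as a covariate the progenitor median was -0.27 (adjusted p = 0.237), and that of the neurogenesis list turned to 0.57 (0.000122; adjusted p = 0.24 with an estimated correlation). Neither list passed with the Y-linked score, where the medians were -0.29 (adjusted p = 0.911) and 0.40 (0.396). Lhx2, Elavl4 and Hes6 lost their calls without wild-type replicate 2 or either knockout array, and Lhx2 without wild-type replicate 1 (0.0688 to 0.239), while Neurod1 passed without wild-type replicate 1 (0.04) or heterozygous replicate 1 (0.038).

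In the neural crest and pharyngeal arch list 4 of 15 genes fell and 11 did not pass, or 4 fallen and 1 risen when adjusted over the list alone (median -0.32, camera, adjusted p = 0.0401; adjusted p = 0.131 with an estimated correlation). All 4 are transcription factors of head mesenchyme: Prrx1 (-1.45, limma, adjusted p = 0.00928), Barx1 (-1.02, 0.027), Twist1 (-0.95, 0.00657) and Prrx2 (-0.80, 0.0242). The camera call was lost without wild-type replicate 1 (0.156), heterozygous replicate 2 (0.0621) or knockout replicate 2 (median -0.14, 0.0613), and with the visceral endoderm score as a covariate (median -0.45, adjusted p = 0.0859) or the Y-linked score (-0.071, 0.401). Each of the 4 genes lost its call without wild-type replicate 2 or either knockout array, Prrx2 also without wild-type replicate 1 and Barx1 without heterozygous replicate 3 (limma, adjusted p 0.0502 to 0.246). In the endothelium list 3 of 19 genes fell and 16 did not pass, with 3 fallen when adjusted over the list alone (median -0.17, camera, adjusted p = 0.00679; adjusted p = 0.11 with an estimated correlation). They were the surface proteins Emcn, endomucin (-1.23, limma, adjusted p = 0.00848), Cd34 (-1.20, 0.0062) and Plvap (-0.92, 0.0144), while the receptor Tie1 did not pass (-0.62, 0.266). All 3 lost their calls without wild-type replicate 2 or knockout replicate 2, and Plvap also without wild-type replicate 1 or knockout replicate 1 (0.0514 to 0.121), and the list did without wild-type replicate 1 (camera, 0.0891). The median was -0.27 without wild-type replicate 2. It was -0.39 with the visceral endoderm score as a covariate (adjusted p = 0.00662; adjusted p = 0.243 with an estimated correlation) and -0.50 with the Y-linked score (0.025; 0.355).

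Cell cycle genes were lower by little. Of 27 measured genes 1 fell, Birc5, the mitotic protein survivin (-0.56, limma, adjusted p = 0.0223), and 26 did not pass, or 2 fallen when adjusted over the list alone (median -0.10, camera, adjusted p = 0.0195; adjusted p = 0.11 with an estimated correlation). Against the heterozygotes the median was -0.02 (camera, adjusted p = 0.465). Ccnd1, cyclin D1 (-0.57, 0.0588), and the mitotic kinases Aurka (-0.39, 0.11) and Aurkb (-0.37, 0.228) did not pass, though Ccnd1 did without heterozygous replicate 1 (0.0192). Birc5 lost its call without any single wild-type or knockout array (0.0782 to 0.185), and the list without wild-type replicate 1 (camera, 0.108). Imprinted genes had a median of 0.21 (camera, adjusted p = 0.00492; adjusted p = 0.108 with an estimated correlation), with 1 of 17 fallen, 16 not passed, and 7 risen and 1 fallen when adjusted over the list alone. Nnat, neuronatin, fell by 0.97 (limma, adjusted p = 0.0186), against the direction of the list, and lost its call without wild-type replicate 2 or either knockout array (0.103 to 0.166). The differences of Phlda2, a growth regulator of the placenta (2.86, 0.0601), Sgce (0.76, 0.055) and Peg10 (-0.64, 0.383) did not pass with all arrays. Phlda2 did without heterozygous replicate 1 (0.00102), and Sgce without that array (0.0441) or heterozygous replicate 3 (0.028). Without wild-type replicate 1 the imprinted list lost its call (camera, 0.124). When the visceral endoderm score was a covariate, the medians were -0.10 for the cell cycle (adjusted p = 0.0155; adjusted p = 0.19 with an estimated correlation) and 0.26 for imprinted genes (0.000409; 0.117). The Y-linked score ended the call of the cell cycle list (median -0.071, adjusted p = 0.432) and gave imprinted genes a median of 0.43 (0.00747; adjusted p = 0.27 with an estimated correlation).

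Other lists did not pass camera. Primitive erythroid genes had 0 of 14 past the threshold (median -0.09, camera, adjusted p = 0.883; 1 risen when adjusted over the list alone), and the median was 0.69 with the visceral endoderm score as a covariate (0.00135; adjusted p = 0.35 with an estimated correlation). Hox genes had 0 of 17 (median -0.17, 0.434; 0 over the list alone), although the list passed without knockout replicate 2 (0.044). Medians changed sign without knockout replicate 1 in the erythroid (0.16), Hox (0.07) and p53 (0.04) lists, and without wild-type replicate 2 in the erythroid (0.08) and p53 (0.004) lists, none of them called. Partners of ADNP and chromatin regulators had 0 of 19 (median -0.09, 0.241; 3 fallen over the list alone), with Smarcd1 (-0.59, limma, adjusted p = 0.0633), Smarce1 (-0.40, 0.0966), Ehmt2 (-0.36, 0.0859) and Ctcf (0.31, 0.159) farthest from 0. Smarcd1 passed without heterozygous replicate 1 (0.0363). Of 8 pluripotency and primitive streak genes 1 rose, Sp5, a target of Wnt signalling (1.46, adjusted p = 0.00848), and 7 did not pass (median 0.22, camera, 0.0869; 1 risen over the list alone). This median ran from 0.11 to 0.22 with an array left out. It was -0.45 with the visceral endoderm score as a covariate (camera, adjusted p = 0.325). Lefty1 (0.69, limma, 0.592; -0.34 without wild-type replicate 2), Dnmt3b (0.47, 0.35) and Fgf8 (0.39, 0.693) were the next largest. Sp5 lost its call without wild-type replicate 2 or either knockout array (0.0597 to 0.097). Of 16 p53 targets 1 rose, Ddit4 (1.62, SE 0.16, adjusted p = 0.000744), which low oxygen also induces, and 15 did not pass (median -0.02, with camera in the other direction, 0.761; 1 risen and 1 fallen over the list alone). Trp53inp1 (0.64, limma, 0.188), Btg2 (-0.54, 0.208) and Perp (0.47, 0.277) did not pass.

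The remaining lists had too few measured genes for a set test. In the trophoblast list Krt7, a keratin, rose (1.07, limma, adjusted p = 0.0223), and Plac1 (0.84, 0.0596) and Tfap2c (-0.10, 0.923; 0.08 without knockout replicate 2) did not pass, with 2 risen when adjusted over the list alone. In the decidua list Wnt4, a secreted signalling protein, fell (-1.26, adjusted p = 0.0371; 1 fallen over the list alone), while Prl8a2 (1.55, 0.548; 828.6 in heterozygous replicate 1, 16.2 to 138.4 on the other arrays), Alpl (0.42, 0.256) and Hoxa11 (0.00, 0.996) did not pass. Krt7 lost its call without wild-type replicate 2 or either knockout array (0.121 to 0.194), and Wnt4 without either wild-type array, heterozygous replicate 2 or 3, or knockout replicate 1 (0.0527 to 0.242). Of 2 macrophage genes 0 passed. Of 2 sex-linked genes Kdm5d passed and Xist, the RNA of the inactive X chromosome, did not (-2.20, adjusted p = 0.292), with 1 risen over the list alone.

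**Figure D3:**
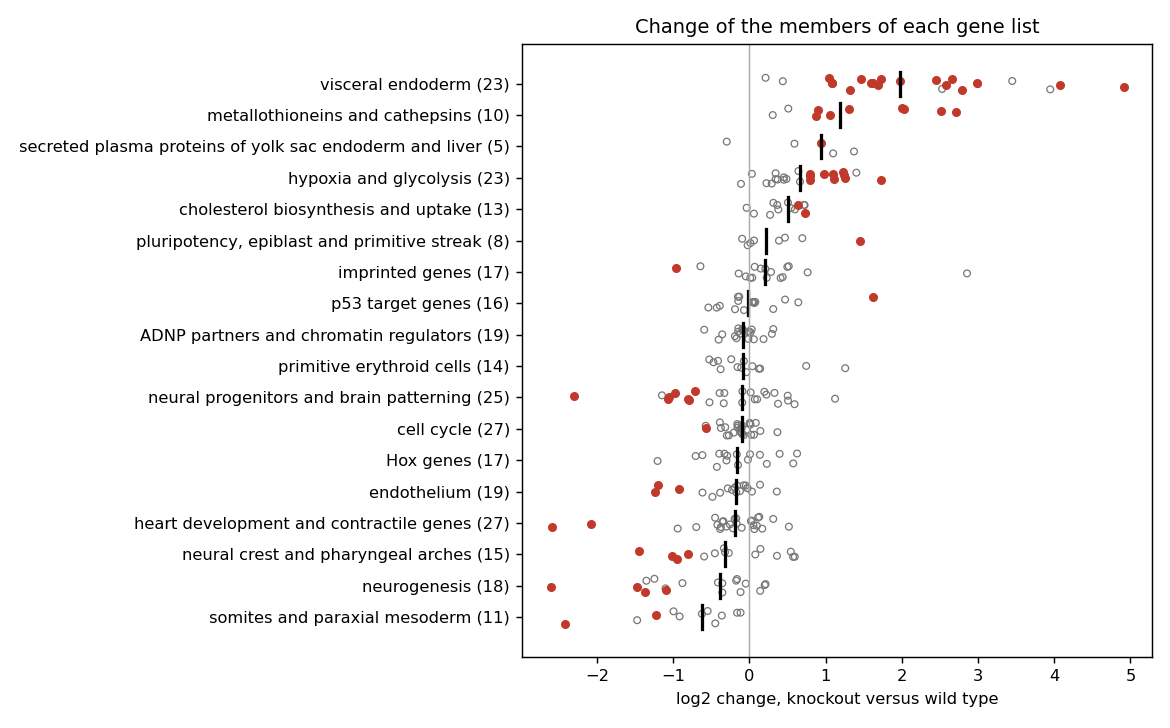
Log2 change between knockout and wild type (horizontal axis, on the log2(signal + pseudocount) scale) of each measured member of the 18 tested gene lists (vertical axis, number of genes in brackets). Filled red points passed the threshold, open points did not, and black bars are medians, which run from -0.62 for somites to 1.98 for visceral endoderm.

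Heterozygous embryos, which keep 1 copy of Adnp, were compared with wild type to ask whether that copy suffices. By limma 0 of 8019 genes passed (smallest adjusted p = 0.301), and 284 (3.54%) had an unadjusted p under 0.05, fewer than the 401 given by chance. The smallest p-values among higher genes belonged to Kdm5d (log2 difference 2.59, adjusted p = 0.301), the imprinted noncoding RNA Rian (0.79, 0.78), Cd99 (0.64, 0.999), Arpc4 (0.69, 0.999) and Upf1 (0.86, 0.999). Among lower genes they were Parp1 (-0.48), Tex9 (-0.82), Psma4 (-0.50), Slc38a1 (-0.50) and Hspa8 (-0.36), each with an adjusted p of 0.999, and none of these 10 passed. In simulated data the same fit recovered 72% of genes changed 2-fold and 16% of those changed 1.5-fold, so small changes could be missed.

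Cell cycle genes were the list that passed camera in the heterozygotes, with a median log2 difference of -0.08 over 27 genes, 0 of them past the threshold or past it when adjusted over the list alone (adjusted p = 0.0256; adjusted p = 0.459 with an estimated correlation). Visceral endoderm genes had a median of -0.13 (camera, adjusted p = 0.366), and low-oxygen and glycolysis genes one of 0.01 (0.815). The number of lists past camera was 3 and 5 without wild-type replicate 1 and 2, and 2 without heterozygous replicate 1 or 2.

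The log2 changes of heterozygotes and knockouts against the same wild-type arrays correlated with Pearson's r = 0.239 and Spearman's rho = 0.271 across genes, which are not independent replicates. Simulated unchanged groups that shared simulated wild-type arrays gave a mean r of 0.55. The simulated knockouts held no changes, unlike the real ones, so the values of r cannot be compared. The observed covariance of 0.0199, which can be, was below the simulated 0.0225. With the wild-type arrays divided between the comparisons, r was -0.24 or 0.154. No shared change was measurable in this way.

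Knockout and heterozygous embryos differed in 470 genes, of which 249 were higher in the knockout and 221 lower. The largest rises were those of the visceral endoderm genes Apoa1 (log2 5.14, SE 0.82, limma, adjusted p = 0.00714), Apoc2 (4.92, SE 1.15, 0.0365), Cubn (4.57, SE 0.48, 0.000837) and Ttr (4.20, SE 0.96, 0.034), and of Spink1 (3.99, SE 0.75, 0.0145). Trp53rka (-2.68, SE 0.33, adjusted p = 0.00191), Myl2 (-2.66, SE 0.16, 3.87e-05), Elavl3 (-2.63, SE 0.44, 0.00882), Rad51c (-2.50, SE 0.39, 0.00714) and Pax1 (-2.45, SE 0.24, 0.000577) were the largest falls. The 18 spike-in control probe sets all read higher on the knockout than the heterozygous arrays (median log2 0.61, 3 past the threshold). Both genotypes had Y-linked signal on every array, and with the Y-linked score as a covariate 144 genes passed, Cubn (4.03, adjusted p = 0.00422) and Myl2 (-2.75, 0.000454) among them. None (0) passed with the visceral endoderm score as a covariate. The count was 246 without heterozygous replicate 3, 78 without knockout replicate 1 and 67 without knockout replicate 2. Cubn, Trp53rka, Myl2, Rad51c and Pax1 passed whichever array was left out. Apoa1, Spink1, Elavl3, Apoc2 and Ttr lost their calls without either knockout array (adjusted p 0.0645 to 0.199), Apoc2 and Ttr also without heterozygous replicate 3 (0.0806 and 0.0986), and Ttr without heterozygous replicate 1 (0.0716).

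Gene lists were also compared between knockout and heterozygote, on the same knockout arrays, so these values are not a separate replicate of those against wild type. In the visceral endoderm list 20 of 23 genes rose and 3 did not pass, or 22 risen when adjusted over the list alone (median 1.98, camera, adjusted p = 7.81e-24; adjusted p = 0.101 with an estimated correlation). Of the low-oxygen and glycolysis genes 16 of 23 rose and 7 did not pass, or 21 over the list alone (median 0.64, 1.28e-18; adjusted p = 0.0402 with an estimated correlation), and of metallothioneins and cathepsins 7 of 10 rose and 3 did not pass, or 8 over the list alone (median 1.17, 7.94e-13; adjusted p = 0.0273 with an estimated correlation). The visceral endoderm list and the metallothionein and cathepsin list are those the study named, and not independent evidence. Of the somite genes 5 of 11 fell and 6 did not pass, or 7 over the list alone (median -0.69, 1.11e-05; adjusted p = 0.0484 with an estimated correlation). Of the heart genes 5 of 27 fell and 22 did not pass (median -0.11, 0.0143; adjusted p = 0.433 with an estimated correlation). In all 13 of 18 lists passed camera in each of the knockout comparisons, 4 against wild type and 3 against the heterozygotes with an estimated correlation. By fry 11 passed against wild type and 10 against the heterozygotes. The heart (fry, adjusted p = 0.0937) and neurogenesis (0.213) lists did not pass fry against wild type. The 13 past camera were not the same lists. Pluripotency and primitive streak genes passed only against the heterozygotes (median 0.50, camera, adjusted p = 0.00967; adjusted p = 0.211 with an estimated correlation). Cell cycle genes passed only against wild type.

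Against both other genotypes 217 genes changed in the same direction, 127 up and 90 down, and 0 in opposite directions. This was 81.6% of the genes that passed against wild type. Both comparisons use the same knockout arrays, which alone raises such an overlap. Rhox5, Mt1 and Bnip3 rose and Myl2, Nppa and Pax1 fell in both. The count was 54 without wild-type replicate 2, 60 without knockout replicate 1 and 33 without knockout replicate 2, and 0 with either score as a covariate.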

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

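Of the tests in this part, those of the spike-in, MURINE_b1 and MURINE_B2 probe sets, of the correlation within the visceral endoderm list and of the erythroid and endothelial lists were chosen after the results they bear on were seen, and the test of genes near Adnp was changed to leave out Trp53rka after its first value was seen. The comparisons of MURINE_B2 with the spike-in range and of Trp53rka with a level midway between wild type and knockout were also chosen after seeing the data. So was the rule that weighs the mean of the hypoxia and glycolysis list beside its median: the mark set before the test was the median alone. All fits with a covariate were added after seeing the data.

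The array's control probe set MUR_b2, which matches a mouse B2 repeat and was not among the genes tested, read 3.92-fold higher in the knockout than in wild type: 863.4 ± 81.5 against 221.0 ± 59.9 (SD, n = 2 each; log2 1.97, SE 0.25, limma, adjusted p = 0.00394), with 263.2 ± 82.5 in the heterozygotes (n = 3). Brighter controls in general are argued against by the 18 spike-in probe sets, whose median difference was 0.17 against wild type, and a rise of repeats in general by the B1 repeat set MURINE_b1, with 0.03 (SE 0.25). The difference was 0.74 (SE 0.31) with the visceral endoderm score as a covariate, so the visceral endoderm in the pools may account for part of it. That score did not overlap between knockout and wild type, so how large a part stays open. A release of B2 repeats without ADNP stays open: the other B2 set, MURINE_B2, differed by 0.34 (SE 0.13, limma, adjusted p = 0.196), where the spike-in probe sets differed by 0.06 to 0.35, and by 0.56 against the heterozygotes (adjusted p = 0.0258), where their median was 0.61. It read 7804.8 and 7629.2 on the knockout arrays, whose highest signals were 8015.3 and 7712.7, so a rise as large as that of MUR_b2 would have gone beyond the top of these arrays.

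The labels say that yolk sac and amnion had been removed, yet yolk sac endoderm left on embryos in varying amounts may account for the rise of the visceral endoderm genes: they also varied together within genotypes, with an estimated correlation of 0.55, though neurogenesis genes did so too (0.703), so this is not particular to yolk sac. Whole yolk sac with its blood islands would bring erythroid genes, whose median difference was -0.09, with a sign that changed when wild-type replicate 2 or knockout replicate 1 was left out, and endothelial genes, which were lower (median -0.17, camera, adjusted p = 0.00679; adjusted p = 0.11 with an estimated correlation), but embryos hold many cells of both types, so a small share cannot be told apart. With the score of these genes as a covariate the median of the hypoxia and glycolysis list went from 0.66 to 0.26 and its mean from 0.72 to 0.42, while Bnip3 went from 1.73 to 1.66, so how far the endoderm share accounts for that rise stays open. The somite median was -0.77 with the score and -0.62 without it. With the score the hypoxia and somite lists both passed camera (adjusted p = 7.37e-05 and 3.22e-05) but not with an estimated correlation (0.106 each). The score did not overlap between the knockout and the other arrays, so this fit cannot decide whether that share accounts for the somite fall. A larger share of visceral endoderm in knockout embryos, by their own growth, is a biological explanation that was not tested. Embryonic day 9 was the only measure of age used here. Whether the genotypes differed in stage was therefore not tested either, for these genes or for the heart, somite and neural genes that fell.

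Trp53rka fell by 2.72 on the log2 scale and lies in the neighbourhood of Adnp. Genes near a targeted locus can differ with DNA carried along from the targeted cells, which would raise the calls among neighbours. Of the 99 other measured genes nearest to Adnp, 50 on either side with Trp53rka left out, 7 passed between knockout and wild type (7.07%) against 258 of 7919 elsewhere (3.26%), an odds ratio of 2.26 (Fisher's exact test, p = 0.0451), or 2.58 with Trp53rka counted (p = 0.0177). Between knockout and heterozygote the odds ratio was 1.42 (Fisher's exact test, p = 0.383). The neighbours called against wild type include Ctsz and Ctsa, of a list that rose, and Tcfl5, also weighed as a germline gene. The others were Snai1 (log2 -1.23), Sulf2 (-0.89) and Dido1 (-0.88), which fell, and Sdc4 (1.31), which rose. Against DNA acting per copy, Trp53rka read 85.4 ± 29.9 in the heterozygotes (SD, n = 3), near the 84.7 of wild type and above the 47.3 midway to the knockout, so carried-along DNA and an effect of ADNP both stay open.

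In heterozygous replicate 1 the control probe sets for the 3' and 5' ends of 18S ribosomal RNA read 1099.8 and 318.4, above the other 6 arrays, and Prl8a2, of the decidua list, read 828.6 there against 16.2 to 138.4 on the others. The probe set for the middle of 18S ribosomal RNA read 72.1 and 86.8 in the knockout against 37.3 and 19.8 in wild type (log2 1.41, SE 0.56, limma, adjusted p = 0.213), and that for its 5' end was 3.48-fold higher (adjusted p = 0.318). The ratio of the 3' to the 5' probe set of actin was 1.16 and 1.19 on the knockout arrays and 0.99 to 1.11 on the other 5. The spike-in probe sets had a mean log2 signal of 8.13, 8.83 and 8.73 on the heterozygous arrays, 9.04 and 9.00 on the wild-type and 9.21 and 9.20 on the knockout arrays. Their median log2 difference was 0.61 between knockout and heterozygous, where 3 of 18 passed the threshold, and -0.45 between heterozygous and wild type, where 0 passed. Of the probe sets with no gene symbol or several, 24 passed the threshold between knockout and wild type.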

How the results depend on the processing

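Fits with the visceral endoderm or Y-linked score as a covariate, and counts without the members of the endoderm, plasma protein and metallothionein lists, were chosen after seeing the data, the other alternatives before. Over the alternatives the lists of knockout versus wild type stayed on their side of camera's threshold with no called direction turned in 324 fits, lost the threshold in 27, gained it in 3 and turned in 4. For genes named by the rule these numbers were 1869, 259, 46 and 17. Among the first, the median changed sign in 14 of the 324 and the log2 difference in 26 of the 1869, 5 and 2 of them with an array left out and 7 and 24 with a covariate. Hes6 lost its call with no filter on dim probe sets (adjusted p = 0.0507), the mean of probe sets (0.0613), the replicate block (0.0806) and both covariates (0.84 and 0.984). The cause was not tested except where fewer arrays, a stricter threshold or a score that differs with genotype leaves less to test. Signal over background limits the dim genes, for which no detection calls were used here.

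The 266 genes of knockout versus wild type became 161 with no filter on dim probe sets, 174 with no intensity trend, 514 with array weights, 137 with a 2-fold minimum, 562 at an adjusted p under 0.1, and 0 with either covariate, and ran from 36 to 417 when an array was left out. The 470 of knockout versus heterozygous became 306, 262, 164 and 962 with no filter, no trend, the 2-fold minimum and the looser threshold, 0 and 144 with the visceral endoderm and Y-linked scores, and 67 to 545 with an array left out. The 217 shared by both became 137, 142, 382, 110 and 466 with no filter, no trend, array weights, the 2-fold minimum and the looser threshold, 0 with either covariate, and 33 to 250 with an array left out. The 0 of heterozygous versus wild type became 1 with the visceral endoderm score and stayed 0 (0 to 0 with an array left out) otherwise. The probe set shared by Adnp and Dpm1, at 0.89, went to 1.24 (adjusted p = 0.12) and 1.77 (adjusted p = 0.50) with the 2 covariates and 0.79 to 0.98 with an array left out.

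With the replicate number as a block, 72 genes passed between knockout and wild type, 76 between knockout and heterozygous and 55 in both. Arrays with the same number did not deviate together (r of deviations -0.294 to 0.005). In groups of 2 arrays the deviations mirror each other, so few of these values are free. They cannot settle whether the numbers pair the samples.

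The 13 lists past camera against wild type became 7 with the Y-linked score, 4 with an estimated correlation and 7 to 13 with an array left out. The 13 against the heterozygotes became 3 with an estimated correlation and ran from 12 to 14. The 1 of heterozygous versus wild type became 0 with no filter, quantile normalization, no trend, array weights, the mean of probe sets, an estimated correlation or fry, 3 and 2 with the 2 covariates, and 1 to 5 with an array left out.

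Values that passed the threshold with or without the alternative and turned direction did so with a covariate, except the progenitor median (0.016 with no filter, camera's direction unchanged). With the Y-linked score these were the visceral endoderm list (-0.067), the neurogenesis list (0.402), Spink1 (-0.45), Kdm5d (-0.36), Rbp4 (-2.03), Trp53rka (0.29), Sst (0.36), Nefl (0.02), Krt7 (-0.19) and Nnat (0.07). For the visceral endoderm score they were, against wild type, the erythroid list (0.685), the neurogenesis list (0.571), Apoa1 (-0.24), Spink1 (-0.24), Rbp4 (-0.95) and Nefl (0.16), and against the heterozygotes Apoa1 (-0.50), Apoc2 (-2.99), Ttr (-2.45), Spink1 (-1.15) and Elavl3 (0.10). Ttr (-2.61 and -5.39) and Apoc2 (-3.26 and -3.74), which had not passed against wild type, also turned there with the visceral endoderm and Y-linked scores, as did the Hox (0.018 and 0.326) list, and the erythroid list with the Y-linked score (0.557). Kdm5d is itself part of the Y-linked score, and Apoa1, Rbp4, Apoc2 and Ttr are part of the visceral endoderm score. With its own score the mean change of the visceral endoderm list is 0 by construction. Turns of genes under a score that holds them are therefore no evidence about those genes. The Y-linked score also set the heterozygotes apart from wild type, where 0 genes passed, so turns with it do not show an effect of sex.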

Other observations

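The test of germline genes in this part used a list put together after the rises of Rhox5, Tex19.1, Fmr1nb and Tcfl5 were seen, though before the values of its own genes were looked at.

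The rises of Rhox5, Tex19.1, Fmr1nb and Tcfl5 may be part of a wider release of germline genes in the knockout, which is a hypothesis. With the visceral endoderm score as a covariate their log2 changes were 2.51, 2.69, 1.40 and 1.45, and none passed (limma, adjusted p 0.0933 to 0.489). How far the visceral endoderm in the pools accounts for these rises therefore stays open. Tcfl5 is also among the called neighbours of Adnp, so its rise bears on carried-along DNA too. A list of 32 genes known mostly from germ cells was tested without the filter on dim probe sets, and 24 of them had a probe set. Their median log2 difference was 0.38, with 16 of 24 positive and a 75th percentile of 1.10, and camera placed the list above other genes. On its own 1 passed, Rnf17, which was higher (1.57, limma, adjusted p = 0.0484). The median fell short of the 0.5 set as the mark of a general release, and the median knockout signal of these genes was 11.0, so dim signals leave the hypothesis open.

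The sexes of the pooled embryos can be read from the Y-linked Kdm5d and from Xist. Kdm5d read 10.0 and 4.3 in the wild-type pools, 46.7, 90.3 and 50.1 in the heterozygous pools and 55.3 and 102.9 in the knockout pools. Xist read 801 and 844.4, then 595, 62.0 and 548.2, then 510.3 and 58.8 in the same order. Both wild-type pools thus lacked clear Y-linked signal, and heterozygous replicate 2 and knockout replicate 2 had little Xist. By these signals those pools were not clearly mixed in sex, though the labels call the pools so.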
